A study of Glycine max with 4 samples.

How the data were processed

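Small RNA was profiled in 4 soybean libraries, 1 each from carpels, stamens, petals and whole flowers, and tissues were taken from the labels. Per the labels' protocols, flowers were collected at a reproductive stage, RNA was extracted with Trizol, and about 10 µg of total RNA was sent for sequencing. RNA of 20 to 30 nt was purified on acrylamide gels, adapters were ligated to both ends, and the cDNA was amplified by PCR. The labels' protocol and the series design name different Illumina instruments, so the instrument is uncertain. The authors deposited, for each library, a list of distinct sequences with the count of reads of each, with no normalization. Sequences were 10 to 32 nt long, so adapters had been removed before deposit. The trimming tool, any quality filter and any genome build are not given in the sources used here. Between 86.0% and 87.2% of the sequences in a library had a single read, and 1.07% to 1.11% of reads held an undetermined base.

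Levels were computed from these counts as RPM, reads per 1000000 reads of 18 to 30 nt. A read of 19 to 24 nt was assigned to a family when its first 18 nt equalled those of a listed mature member, which leaves 3' length variants in the family and merges members that differ near the 3' end. The 75 mature sequences of 47 families, the 6 control sequences and the functional groups were written down from general knowledge before the data were examined, without a database, so members missing from the list were not counted. Families with near-identical members cannot be split into loci. Of the listed families, 41 had a gene of that name in the RefSeq table of the Glycine_max_v4.0 assembly, which names 659 microRNA genes. No genome was used, so positions, annotated mature microRNAs and shares of ribosomal, transfer or organelle RNA were not analysed here.

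A family was called higher or lower in a whorl when it had at least 100 reads in the highest whorl library and its RPM was at least 2 times, or at most 1/2 of, that in each of the other 2 whorls. Whole flowers were called above or below the whorls at 1.5-fold. Named families were fixed by rule before the data were examined. They were the 10 most abundant families, up to 10 per direction and whorl ranked by the smaller ratio, up to 5 above and 5 below for whole flowers, and all members of the pollen and phased siRNA group and of the controls. miR390 was the 11th family lower in carpels, outside that limit, and was named there after its values were seen, as were the families named only under a group or an alternative. Groups of at least 3 tested families were described by the median log2 ratio of a whorl to the mean of the other whorls, with a pseudocount of 0.5 reads and its percentile among 10000 random lists matched on level. Percentiles up to 2.5 or from 97.5 were taken as outside. With 1 library per tissue, no test between tissues was made.

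A count of 0 was taken to allow 3 counts, which is 0.952 RPM in carpels, 1.44 RPM in stamens, 1.02 RPM in petals and 1.13 RPM in whole flowers. The alternatives were 4 other scalings, 2 other ways of matching, 2 other read minimums and 2 other fold limits. The scalings were reads of 20 to 22 nt, family reads, TMM factors from edgeR 4.0.16 and size factors from DESeq2 1.42.0, the last 2 computed over the families. On simulated counts with the real depths, the size rule recovered 99.1%, 97.9% and 99.4% of families raised 2.5-fold in carpels, stamens and petals over 28 families, and all raised 4-fold. It called 0% of unchanged families, and intervals for folds held the true value in 95.5% of draws. These simulations held counting error only. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3 were used.

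After the family results, overlapping carpel reads of 20 to 24 nt with at least 3 reads were joined by shared stretches of 15 nt into transcripts. Joining started from unlisted 22 nt sequences with at least 20 carpel reads and at least 4-fold the RPM of both other whorls. The transcript holding the most starting reads was kept, and reads of 18 to 26 nt that matched it perfectly on either strand were counted. On simulated transcripts, a median of at least 99.8% of the length was rebuilt. Each was simulated alone, without reads of other transcripts, so wrong joins between related transcripts were not tested. This step and the comparison of sequences within families were chosen after the data were examined.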

Results

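Small RNAs were sequenced from carpels, stamens, petals and whole flowers of soybean (Glycine max). The plants were of the cultivar Urano and were grown in the field. Each tissue was represented by 1 library made from a pool of material, so no difference below has a replicate check and no p-value is given. The carpel library held 3362896 reads, the stamen library 3128483, the petal library 3249580 and the whole flower library 3072855. Of these, 3149795, 2080150, 2928379 and 2655250 reads were 18 to 30 nt long, and levels are given as reads per 1000000 of them (RPM). Intervals are exact 95% intervals (Poisson for levels, conditional binomial for folds, Clopper-Pearson for shares). They cover counting error only and leave out variation between samples and libraries. PCR reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error.

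The first comparison asked which size classes of small RNA each tissue held. In plants, most microRNAs are about 21 nt long, and the 24 nt class is mainly formed by siRNAs that direct DNA methylation. Carpels had the highest share of 24 nt reads, 44.4% (44.3 to 44.4), and a 21 nt share of 15.7% (15.7 to 15.8). In petals the classes were closer together, with 28.5% at 21 nt (28.4 to 28.5) and 30.6% at 24 nt (30.6 to 30.7). Whole flowers had 21.6% at 21 nt and 36.4% at 24 nt. Stamens had 21.4% at 21 nt and the lowest 24 nt share, 15.8% (15.8 to 15.9). The stamen library also held the most reads outside 20 to 24 nt, 59.7% of all its reads against 17.8% in carpels, 24.9% in petals and 25.8% in whole flowers. T was the leading 5' nucleotide of 21 nt reads, at 59.5% in carpels, 58.0% in stamens, 62.0% in petals and 58.9% in whole flowers. A led the 24 nt reads, at 47.0%, 38.0%, 39.9% and 45.5% in the same order. When distinct sequences were counted in place of reads, the 24 nt share was above the 21 nt share in all 4 libraries, at 60.5% in carpels, 45.4% in stamens, 55.6% in petals and 57.3% in whole flowers. Over sequences with at least 2 reads the order turned in petals, with 39.6% at 21 nt and 13.9% at 24 nt, and in whole flowers, with 30.9% and 17.8%. Over reads of all lengths, the 21 nt share was 14.7% in carpels and 14.2% in stamens.

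**Figure D1:**
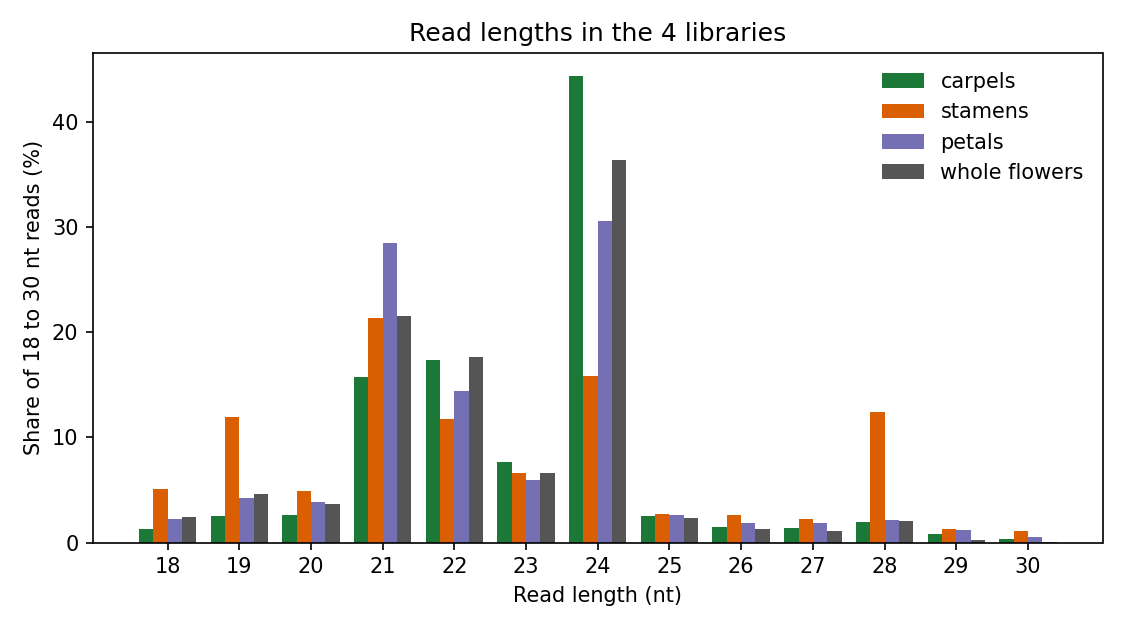
Share of 18 to 30 nt reads (vertical axis, percent) at each read length (horizontal axis, nt) in the 4 libraries, 1 bar per library. Carpels stand highest at 24 nt with 44.4%, petals stand highest at 21 nt with 28.5%, and stamens have 15.8% at 24 nt.

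Reads were assigned to 47 families of conserved or legume microRNAs and the trans-acting siRNA tasiR-ARF. Of these families, 44 had a read in at least 1 library. By mean level over the 4 libraries, miR159, which targets GAMYB-type transcription factors, came first with 40206 RPM and 36.1% of the summed level. It was followed by miR165/miR166, a regulator of class III HD-ZIP genes and organ polarity (25241 RPM), and by miR1507, a legume family that targets NLR disease resistance genes (10227 RPM). The other families among the 10 most abundant were miR168 (9699 RPM), miR1511 (5130 RPM), miR169 (4954 RPM), miR319 (3630 RPM), miR167 (2749 RPM), miR1509 (1823 RPM) and miR396 (1727 RPM). Listed families made up 7.01% of the 18 to 30 nt reads in carpels, 11.8% in stamens, 15.7% in petals and 9.98% in whole flowers. With at least 100 reads in a whorl library, 28 families entered the comparisons between whorls, and 21 of them were at least 2-fold apart from both other whorls in at least 1 whorl.

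The comparison of carpels with the other whorls asked which families marked the female organ. miR167 and miR160, which both target auxin response factor genes, were the 2 families higher in carpels. miR167 reached 4586 RPM, 2.25-fold (2.17 to 2.33) its level in stamens and 2.80-fold (2.71 to 2.89) its level in petals. miR160 reached 114 RPM, 2.12-fold (1.71 to 2.64) above stamens and 4.39-fold (3.42 to 5.70) above petals. In the opposite direction, 11 families were lower in carpels. The auxin receptor regulator miR393 had 5.71 RPM in carpels against 39.9 RPM in stamens and 51.2 RPM in petals, and its level in stamens was 6.98-fold higher (4.16 to 12.4). miR396, which targets growth-regulating factor genes, had 232 RPM in carpels, and its level was 6.77-fold higher in stamens (6.24 to 7.34) and 15.8-fold higher in petals (14.6 to 17.02). miR156/miR157, which targets SPL genes of the phase change pathway, had 82.9 RPM in carpels against 360 RPM in stamens and 517 RPM in petals. miR169 had 1423 RPM in carpels against 7591 RPM in stamens and 7256 RPM in petals. miR172, a regulator of AP2-type genes, had 15.9 RPM in carpels against 105 RPM in stamens and 61.5 RPM in petals. The lower group also included miR1510 at 239 RPM and miR1507 at 4656 RPM, both regulators of NLR genes, and the ARGONAUTE1 regulator miR168 at 4257 RPM. miR319, a regulator of TCP genes, was lower in carpels at 1732 RPM, but its direction flipped with DESeq2 size factors. miR2109 at 275 RPM and miR390 at 220 RPM were lower too, but both flipped relative to family reads, with TMM and with DESeq2 size factors.

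Scaling decided much of the carpel result. The median log2 ratio of carpels to the mean of the other whorls over the 28 families was -1.46 relative to 18 to 30 nt reads. It was -1.24 relative to reads of 20 to 22 nt, -0.55 relative to family reads, -0.54 with TMM and -0.37 with DESeq2 size factors. For stamens the 5 medians in the same order were -0.18, -0.03, -0.08, -0.05 and 0.02, and for petals they were 0.69, 0.36, -0.06, -0.10 and -0.33. miR167 and miR160 stayed at least 2-fold higher in carpels under all 4 other scalings. These scalings all raise carpels against both whorls, so a higher call in carpels could not be lost and was not tested by them. Of the 11 lower families, 3 stayed at least 2-fold lower under all 4, namely miR393, miR396 and miR156/miR157. With TMM, the log2 ratio of carpels to the nearer whorl was 1.92 for miR167, 1.83 for miR160, -1.96 for miR393, -2.01 for miR396 and -1.37 for miR156/miR157. The miR167 result also depended on its 3' ends. Relative to 18 to 30 nt reads, counting exact matches to listed sequences turned its log2 ratio to the nearer whorl from 1.17 to -1.74. In the same scaling, exact matching brought miR160 from 1.08 to 0.56 and miR172 from -1.95 to -0.30, inside the 2-fold rule. Against 2 families higher and 11 lower in carpels, 4 were higher and 4 lower relative to family reads and with TMM, and 5 higher and 3 lower with DESeq2 size factors. Against petals alone, without the stamen library, 19 families were lower in carpels.

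Stamens were compared with carpels and petals to find families that marked the male organ. miR399, known from phosphate homeostasis, tasiR-ARF and miR390, which triggers tasiR-ARF production, were the 3 families higher in stamens. miR399 had 83.6 RPM in stamens, 4.54-fold (3.36 to 6.23) above carpels and 3.14-fold (2.39 to 4.16) above petals. tasiR-ARF had 109 RPM, 3.72-fold (2.91 to 4.79) above carpels and 2.29-fold (1.84 to 2.85) above petals. miR390 had 950 RPM, 4.32-fold (3.96 to 4.72) above carpels and 2.08-fold (1.94 to 2.23) above petals. No family was lower in stamens than in both other whorls by the 2-fold rule. Against carpels alone, without the petal library, 12 families were higher and 2 lower in stamens, and against petals alone, without the carpel library, 4 were higher and 8 lower. The 3 stamen families stayed at least 2-fold higher under all 4 other scalings, with log2 ratios to the nearer whorl of 1.43, 1.14 and 1.36 relative to family reads. These scalings all raise stamens against petals, so the ratios to petals could not be lost. Only the ratios to carpels, which the scalings lower, were tested. With TMM and with DESeq2 size factors, 5 families were higher and 1 lower in stamens. The listed tasiR-ARF sequence had 0 exact matches in at least 1 whorl, so that call rests on matching by the first 18 nt. The stamen library differed from the others in composition, with 31.96% of its reads at 10 to 17 nt and 30.9% of its reads in its 10 most abundant sequences, against 7.20% in carpels and 14.6% in petals. Reads of 10 to 17 nt lie outside the RPM total. Within it, stamens had 12.4% at 28 nt, against 1.95% to 2.19% in the other libraries. At 19 nt stamens had 11.9%, against 2.51% to 4.60%. These reads enter the total behind the stamen RPM values and length shares.

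Petals were compared with the reproductive whorls in the same way. 7 families were higher in petals. The legume family miR3522 had 319 RPM, 6.05-fold (5.13 to 7.18) above carpels and 8.62-fold (6.82 to 11.02) above stamens. miR170/miR171, which targets SCARECROW-like genes, had 3376 RPM, 5.997-fold (5.70 to 6.31) above carpels and 6.40-fold (6.01 to 6.82) above stamens. miR396 had 3655 RPM, 2.33-fold (2.24 to 2.42) above stamens. miR159 had 67153 RPM, 3.19-fold (3.17 to 3.22) above carpels and 2.17-fold (2.15 to 2.19) above stamens. miR1515 had 67.3 RPM, and miR394, a regulator of the F-box gene LCR, had 107 RPM. miR1509 had 2729 RPM, but its direction flipped with DESeq2 size factors. miR160 was the 1 family lower in petals, at 25.95 RPM against 114 RPM in carpels and 53.8 RPM in stamens. It stayed lower under all 4 other scalings, but these all lower petals against both whorls, so that call could not be lost. miR3522 and miR170/miR171 stayed at least 2-fold higher under the same 4 scalings, which work against a higher petal level. The other 5 petal families fell below the 2-fold rule relative to family reads, where miR396 had a log2 ratio to the nearer whorl of 0.81 and miR159 of 0.51. Against 7 families higher and 1 lower in petals, 2 were higher and 2 lower relative to family reads, with TMM and with DESeq2 size factors. Against carpels alone, without the stamen library, 19 families were higher and 2 lower in petals, and against stamens alone, without the carpel library, 8 were higher and 4 lower.

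**Figure D2:**
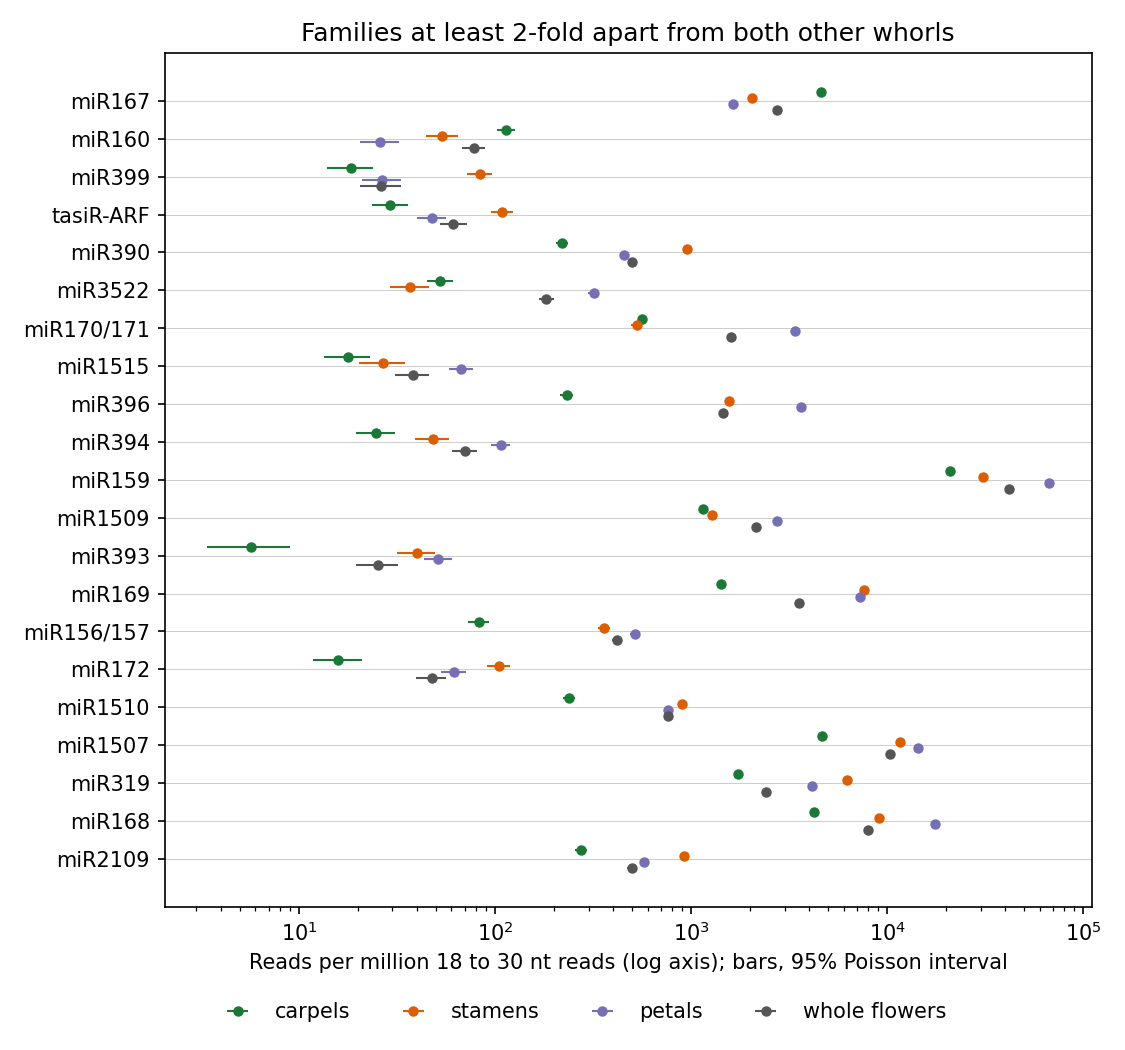
Levels of the families at least 2-fold apart from both other whorls in the 4 libraries (horizontal log axis, RPM; points are single libraries and bars are 95% Poisson intervals for counting error). miR167 stands highest in carpels at 4586 RPM and miR170/miR171 in petals at 3376 RPM, while the lower carpel levels of miR319, miR2109 and miR390 and the higher petal level of miR1509 flip under at least 1 other scaling.

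Whole flowers, which hold the dissected whorls together with the sepals, were compared with the range of the 3 whorls. All 29 families with at least 100 reads in a library lay within 1.5-fold of that range, and 0 lay above or below it. miR167 had 2736 RPM in whole flowers, between 1637 RPM in petals and 4586 RPM in carpels. miR170/miR171 had 1590 RPM, between 527 RPM in stamens and 3376 RPM in petals. miR396 had 1451 RPM, between 232 RPM in carpels and 3655 RPM in petals. miR165/miR166, at 16360 RPM, lay below the lowest whorl, petals with 22674 RPM, but by less than the 1.5-fold limit.

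Families were also grouped by what their targets do. Calls below use RPM, and some failed the 2-fold rule under other scalings. In petals, miR159, miR394, miR396 and miR1509 failed it under all 4 others, as did miR319, miR2109 and miR390 in carpels. miR1515 in petals and miR172, miR1507, miR1510 and miR168 in carpels failed it relative to family reads, with TMM and with DESeq2 size factors. miR169 in carpels failed it with DESeq2 size factors. In the auxin group of 5 tested families, miR160 and miR167 were higher in carpels, miR390 and tasiR-ARF were higher in stamens, and miR160 was lower in petals. miR393 was lower in carpels under every scaling, and miR390 was lower there but flipped under 3 other scalings. The median log2 ratio of this group in petals was -0.54, at percentile 1.31 of 10000 random lists of matched level, but at percentile 11.2 relative to family reads. Of the 5 regulators of NLR genes, miR1507, miR1510 and miR2109 were lower in carpels, and miR2109 flipped under 3 other scalings. miR482 and miR2118 passed the rule in no whorl, and this group lay at percentile 55.5 in carpels, 73.1 in stamens and 11.7 in petals. Of the 3 flowering time families, miR156/miR157 and miR172 were lower in carpels and miR159 was higher in petals, with percentiles of 6.91, 61.1 and 83.3 in carpels, stamens and petals. Of the 6 organ polarity and boundary families, miR396 and, with the same 3 flips, miR390 were lower in carpels, miR390 and tasiR-ARF higher in stamens, and miR394 and miR396 higher in petals, with percentiles of 38.6, 68.2 and 26.2. Of the 5 tested legume families outside the NLR group, miR1515, miR3522 and, with a flip under DESeq2 size factors, miR1509 were higher in petals, with percentiles of 79.2 in carpels, 4.39 in stamens and 85.7 in petals. The remaining 5 groups had fewer than 3 tested families. Among them, miR319 was lower in carpels (flipped with DESeq2 size factors) and miR159 higher in petals in the anther and petal group, miR169 was lower in carpels and miR399 higher in stamens in the nutrient group, miR168 was lower in carpels in the silencing group, and miR170/miR171 was higher in petals among other conserved families.

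Of the 3 families tied to reproductive phased siRNAs or pollen, 1 had enough reads for the 2-fold rule, miR2118, and it passed the rule in no whorl. This family, a trigger of phased siRNAs from NLR genes in legumes, had 806 RPM in carpels, 1098 RPM in stamens, 964 RPM in petals and 966 RPM in whole flowers. miR2275 had 0 reads, which allows up to 0.952 RPM in carpels, 1.44 RPM in stamens, 1.02 RPM in petals and 1.13 RPM in whole flowers. miR845 had 3 reads in carpels, 0 in stamens, 2 in petals and 2 in whole flowers, so a difference was not detectable at this depth. The RefSeq table names no miR2275 or miR845 gene, so their low counts need not come from depth. As background, the 4 Arabidopsis sequences (miR158, miR161, miR163 and miR173) and the animal miR-21 had 0 reads in every library. The animal let-7 sequence had 1 read in carpels, 5 in stamens, 0 in petals and 0 in whole flowers.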

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

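Of the tests in this part, the pairing of strands at a fixed overhang was set out before its result was seen, and the strand, scaling and median tests were chosen afterwards. The transcript, the short reads and the let-7 reads lie outside the family comparisons. There were no control samples, so each was flagged when it was above the 3 counts that a count of 0 allows. That limit is not a measured background level.

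A transcript of 572 nt, rebuilt from overlapping carpel reads, gave 12849 RPM in carpels (12725 to 12975) against 2770 RPM in stamens, 4329 RPM in petals and 9253 RPM in whole flowers. Of its carpel reads, 70.5% were 22 nt long, or 59.2% without the 22 nt sequences used to find it, while 18.2% of all carpel reads of 18 to 26 nt had that length. This was not particular to carpels. Without the sequences used to find it, the 22 nt share was 64.1% in stamens, 70.2% in petals and 66.3% in whole flowers. The reading frames of both strands were searched for the stretch SGAHLNP, which is typical of aquaporin-type channels. It lay in 1 frame, within a run of 86 amino acids without a stop that covers only part of the 572 nt. No other stretch was searched for, so the match does not identify the gene or its protein family. The locus was not placed on a genome. Breakdown of a single-stranded transcript is argued against by the strands, since the less used strand held 42.7% of the carpel reads. The transcript was chosen for reads that were higher in carpels. Without the sequences used to find it, carpels held 3.98-fold (3.86 to 4.10) the level of stamens and 2.40-fold (2.35 to 2.46) that of petals. The remaining reads still match a transcript that was chosen and extended by carpel reads, so these folds are not free of that choice. The 4 other scalings, which all raise carpels against both whorls, gave 4.24-fold to 7.14-fold over stamens and 3.14-fold to 6.72-fold over petals. Scalings that raise carpels cannot lower the ratio, so even the smallest of these values, 3.14, leaves scaling open. Double-stranded RNA cut into 22 nt duplexes predicted a peak of opposite reads at a 2 nt overhang, and these were 1.13 times the median of the other offsets, which argues against it as tested. In simulations, duplexes that kept both strands gave a median of 3.26 and duplexes that kept mostly 1 strand gave 1.07, so loss of a strand stays open, and a difference between the tissues stays open with 1 library each.

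Most families were lower in carpels than in the other whorls. The large 24 nt class of carpels is argued against as the whole cause, because the median log2 ratio was still -1.24 relative to reads of 20 to 22 nt. A shift common to all families may account for much of the pattern and cannot be told apart from lower levels of many single families. Under the 3 scalings set by the families the median nearest to 0 was -0.37, and these scalings assume that most families do not differ. A difference between the tissues stays open and was not tested.

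The stamen library held 31.96% of its reads at 10 to 17 nt, below the gel range that the labels give, against 5.81% in carpels, 9.14% in petals and 13.5% in whole flowers. The animal let-7 sequence had 5 reads in the stamen library, above the limit of 3 counts. It was listed as a background control, so passing this limit does not separate signal from background.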

How the results depend on the processing

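No paired analysis was possible because each tissue had 1 library. The comparisons without 1 of the other whorl libraries were added after seeing the data, and the other alternatives were planned. The planned counts of annotated mature microRNAs and of RNA classes were not run, since no genome was used. The cause of the changes below was not tested, except that a lower minimum or fold limit admits more families and a higher limit fewer. Depth limits families under 100 reads in every whorl, 19 of the 47. Some of these, such as miR2275 and miR845, had no gene of that name in the RefSeq table.

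Families higher in carpels numbered 2, but 4 relative to family reads and with TMM, 5 with DESeq2 size factors, 0 with exact matching and 0 at 3-fold. Families lower in carpels numbered 11, but 4 relative to family reads and with TMM, 3 with DESeq2 size factors, 6 at 3-fold, and 12 to 19 without the petal or stamen library. Families higher in stamens numbered 3, but 5 with TMM and with DESeq2 size factors, 6 at 1.5-fold, 1 at 3-fold, and 4 to 12 without the carpel or petal library. Families lower in stamens numbered 0, but 1 relative to family reads, with TMM and with DESeq2 size factors (miR3522), 1 with exact matching (miR167), 1 with no minimum (miR845), 1 at 1.5-fold (miR164), and 2 to 8 without the petal or carpel library. Families higher in petals numbered 7, but 3 relative to reads of 20 to 22 nt, 2 relative to family reads, with TMM, with DESeq2 size factors and at 3-fold, 14 with a minimum of 10 reads, 15 with no minimum, and 8 to 19 without the carpel or stamen library. Families lower in petals numbered 1, but 2 relative to family reads, with TMM, with DESeq2 size factors, with a minimum of 10 reads and with no minimum, 0 at 3-fold, and 2 to 4 without the stamen or carpel library. Whole flowers lay above the whorls for 0 families, but for 1 with a minimum of 10 reads (miR4376) and 2 with no minimum, and below them for 0 families, but for 1 at a limit of 1 (miR165/miR166).

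The log2 ratio to the nearer whorl reversed to -1.74 for miR167 in carpels with exact matching, which counted a single sequence of that family. It reversed with DESeq2 size factors for miR319 in carpels (0.22) and for miR1509 in petals (-0.24). In carpels it reversed relative to family reads, with TMM and with DESeq2 size factors for miR2109 (0.10, 0.14 and 0.42) and for miR390 (0.11, 0.15 and 0.43). The auxin group in petals moved from percentile 1.31 to 11.2 relative to family reads, 11.2 with TMM and 9.79 with exact matching. Exact matching gave no ratio for tasiR-ARF or miR2109, which had 0 exact matches in at least 1 whorl.

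Length shares in carpels, stamens, petals and whole flowers moved as follows. Over distinct sequences, 21 nt made up 7.81%, 12.8%, 11.6% and 10.7%, and 24 nt made up 60.5%, 45.4%, 55.6% and 57.3%. Over sequences with at least 2 reads, 21 nt made up 23.1%, 24.4%, 39.6% and 30.9%, and 24 nt made up 29.6%, 5.13%, 13.9% and 17.8%. Over all lengths, 21 nt made up 14.7%, 14.2%, 25.7% and 18.6%, and 24 nt made up 41.5%, 10.5%, 27.6% and 31.5%. Without family reads, 21 nt made up 10.9%, 13.2%, 18.2% and 15.1%, and 24 nt made up 47.7%, 17.9%, 36.3% and 40.4%.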

Other observations

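Within families, the sequences that made up the reads differed between whorls, and such shares do not depend on the scaling of the libraries. Of 27 families with at least 50 reads in each whorl, 8 had a sequence whose share of the family differed by at least 20 percentage points between whorls, with intervals that did not overlap. For miR172, AGAATCTTGATGATGCTGCAT made up 93.3% of petal reads, 54.0% of carpel reads and 8.26% of stamen reads, while GGAATCTTGATGATGCTGCAG made up 4.44%, 42.0% and 61.5% in the same order. The carpel shares of miR172 rest on 50 reads. For miR170/miR171, TTGAGCCGCGTCAATATCTCA made up 71.7% of petal reads, 26.5% of carpel reads and 10.6% of stamen reads. For miR399, TGCCAAAGGAGATTTGCCCAG made up 90.2% (84.8 to 94.2) of stamen reads, 79.5% (68.8 to 87.8) of petal reads and 41.4% of carpel reads. The carpel share of miR399 rests on 58 reads. These families were singled out after their values were seen.

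The median over the 20 other families was set out before its result was seen, and its limit to 8 of them, the odds ratios and the test among sequences of 1 length were chosen afterwards. For miR167, TGAAGCTGCCAGCATGATCTTA made up 63.8% of carpel reads and 3.57% of petal reads, while TGAAGCTGCCAGCATGATCTA made up 4.23% and 39.6%. The 22 nt share of miR167 was 38.1 percentage points higher in carpels than in petals. Over the 20 other families the median difference was 0.26 points, but most of them were almost all or almost never 22 nt long. The 8 with a share of 5% to 95% in either library were all higher in carpels, by a median of 3.49 points (0.543 to 8.47, bootstrap over families), with 7 at 8.47 or less and miR170/miR171 at 27.03. Their median odds ratio of a 22 nt read was 1.28 and all 8 lay below that of miR167, 4.999 (4.65 to 5.37), which argues against a size selection for 22 nt molecules in the carpel library as the whole cause, while a smaller shift of that kind stays open. Among sequences of 1 length such a selection is argued against too, since TGAAGCTGCCAGCATGATCTT made up 86.0% (84.9 to 87.0) of the 21 nt miR167 reads in carpels and 6.95% (6.11 to 7.87) in petals, a difference of 79.0 points. A hypothesis left open is that different MIR167 genes may be used in carpels and petals, which was not tested without a genome.

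Unlisted sequences of 20 to 24 nt that passed the same size rule numbered 291 in carpels, 174 in stamens and 375 in petals. In carpels 64.3% of them were 22 nt long, and in petals 45.9% were 21 nt long. Sequences of the rebuilt transcript were not removed, so this carpel share and that transcript may overlap. The counts used RPM alone, and the other scalings were not tried for them. miR828, which targets MYB transcripts, had 44 reads in petals and 31 in whole flowers and 0 in carpels and stamens. Against the limit of 3 counts per library its petal level was at least 15.8-fold higher than in carpels and at least 10.4-fold higher than in stamens, and the exact intervals, which include the counting error of the petal reads, begin at 12.3 and 8.12. It lies below the 100 read minimum and was chosen after its values were seen.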
